A study of Caenorhabditis elegans with 38 samples.

How the data were processed

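Young adult worms of the strain N2 were exposed for 24 h to anatase or rutile titanium dioxide, nano-sized or bulk, at 0.01, 0.1 or 1 mg/L, or kept in water. The protocol also names a higher dose, which has no arrays here and was not used. Total RNA of treated worms and of worms in water was labelled with Cy3 and Cy5 and hybridised together, with the treated sample in Cy5 on some arrays and in Cy3 on others. The series describes 3 separate biological replicates per concentration. The p-values measure the spread between arrays, which the model takes as independent. Arrays of different groups that share a slide and a number in their names correlated across genes at a median of 0.38. Where such arrays stand on the same side of a comparison, the p-values and standard errors may therefore be too small. Where they stand on opposite sides, as in nano-sized against bulk particles, they may be too large. The 38 arrays lie on 11 slides.

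Per the file headers, the authors' image analysis software (version 8.0.0, name not given) subtracted a global mean background, took log2 values of the mean spot signals and normalised the 2 channels of each array by lowess with a smoothing of 0.2. All files had 1 set of header settings. The log2 ratio of an array was the difference of its 2 deposited log2 channel values. A planned correction of raw signals with normexp and loess could not be run, because the files hold values that are already corrected and normalised, and the deposited values were used instead. The series matrix holds log2 ratios made by the authors, per transcript name: tested on the files, each array's oriented ratio had been centred per gene over 11 arrays, 9 of a particle and the 2 water arrays, and the column medians are 0. Of its 26195 names 26138 were found among the probe names. How the authors filtered the names, and in which direction the ratios run, stays unknown. Since this centring removes the mean of a particle, the matrix was used for dose trends alone.

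The direction of the ratios was read from the channel order. On all treated arrays the authors' matrix is turned in the same way, and this order was taken as treated over water; it is likely but not stated, and with the other reading every sign would turn. Of 295 pairs of treated arrays with the same dye, 5 correlated across genes below -0.3, the lowest at -0.49. Pairs with the same dye cannot test the direction. Of 34 pairs of arrays of 1 group, 5 lay below -0.3, the lowest at -0.52. Of the 11 such pairs with the same dye 0 did, so these 5 had opposite dyes. All 5 were rutile pairs, and the cause was not tested. Genes are not independent replicates.

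One scan had been deposited under 2 samples, anatase nano 0.01 mg/L replicate 2 and anatase bulk 0.01 mg/L replicate 3. The files name the same images, and their values correlated at 0.77 across 43803 spots of genes (highest of the other pairs 0.5) and at 0.67 across 757 negative control and dark corner spots (highest of the others 0.26). The scan was counted once, as the bulk sample, whose slide and array the image names point to. This choice was made before any model was fitted, and it leaves 37 arrays where the plan had 38.

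Of 43603 distinct probes, 34987 were matched to a gene by sequence name and 315 by transcript accession in the RefSeq annotation of WBcel235, and 8301 were not matched. Probes were kept if they lay above the 99th percentile of the negative controls of an array in either channel on at least 3 arrays, which left 25405 probes. A gene with several probes, as 4037 genes had, was represented by the probe with the highest mean intensity. Genes needed values on at least 2 arrays in every group, and 15561 genes were tested, 8375 of them with a symbol. Between 9.3% and 23.5% of the spots of an array carried a quality flag of the software, and these spots were kept. The number of arrays limits the precision.

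One linear model per gene was fitted to the log2 ratios of all 37 arrays with limma 3.58.1 in R 4.3.3, with a coefficient for each of the 12 treated groups and a dye term. Moderated variances used a prior standard deviation of 0.604 on the log2 scale with 8.2 prior and 24 residual degrees of freedom. Contrasts gave each particle and dose against water, the mean of each particle over its doses, nano-sized against bulk particles over the doses and at each dose, the linear trend per 10-fold of dose, anatase against rutile, and the difference between the nano-sized and bulk contrasts of anatase and rutile. The p-values were two-sided and adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. Standard errors come from the model. The 29 gene lists were tested with camera of limma at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over 290 list results. With an estimated correlation 0 of the 65 called list results passed. Group sizes of 3 arrays were not tested for outlying arrays.

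Comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule takes, for each particle mean, the 10 genes with the largest rise and the 10 with the largest fall among those that passed with the same sign on at least 8 arrays, up to 5 each way for the other main contrasts, up to 2 members of a list with the smallest p in each direction, and a set of stress and metabolism genes given whatever their test. Genes without a symbol were left out of this rule. Where a contrast called 5 genes or fewer, these were named as well, a choice made after the values were seen.

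The procedure was tested on simulated data by adding known changes to 50 genes per size in the arrays of nano-sized anatase. It called 8%, 68%, 98% and 98% of genes changed by 0.5, 1, 1.5 and 2 on the log2 scale, with median sizes of 0.49, 0.99, 1.49 and 1.93, and 5 of the 141 genes called were unchanged ones. The simulated noise was independent between genes and arrays. The real arrays correlate, so the share of false calls in the real contrasts cannot be read from this test. For blocks, the correlation within slides was estimated at 0.17 with duplicateCorrelation, which uses statmod 1.5.0. A replicate block was formed from the running number of the sample titles, and another from the number after the dose in the array names. For nano-sized and bulk arrays of the same number and dose, the deviations from their group means were correlated across genes. With the title numbers the value was above 0.1 in 5 of 8 anatase pairs (-0.38 to 0.67) and in 9 of 9 rutile pairs (0.26 to 0.69). With the array-name numbers this held in 7 of 8 anatase pairs (-0.10 to 0.67). Deviations within a group sum to 0, so these pairs are not independent. The alternatives comprised 11 planned and 7 added settings and 37 fits that each left out 1 array. Numbers of alternatives given for list calls leave out the estimated correlation, which ended every list call. They also leave out slide as a random block, for which camera was not run. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.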

Results

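Transcript levels were measured with 2-colour oligonucleotide arrays in the wild-type nematode strain N2 after 24 h in water with titanium dioxide. The particles were anatase or rutile, the 2 common crystal forms of this oxide, each as a nano-sized and as a bulk powder, at 0.01, 0.1 and 1 mg/L. Each of the 12 combinations had 3 arrays, and on each array RNA of treated worms was hybridised beside RNA of worms kept in water. A further 2 arrays compared water with water. Of the 38 arrays, 37 were used, because 1 scan had been deposited under 2 samples, and anatase nano at 0.01 mg/L therefore had 2 arrays. Between 18.3% and 58.7% of the spots of an array lay above its negative controls, and 15561 genes were tested. The small number of arrays per group limits the precision of every value.

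The water arrays gave the background of the comparison. On them 2341 and 1692 genes differed by at least 1 on the log2 scale between the 2 channels. The 35 treated arrays had 937 to 5088 such genes, with a median of 2158. Gene groups also moved on these arrays. The oocyte and eggshell genes had medians of 0.58 and 0.83 on the 2 water arrays, the vitellogenins, which encode yolk proteins, 0.43 and 0.62, and the lysozymes and antimicrobial peptides -0.76 and -0.52. The cuticle collagens had -0.17 and -0.09, the histones -0.22 and -0.21, the sperm proteins -0.30 and -0.03 and the proteasome genes 0.26 and 0.27. Medians of up to 0.83 in size thus occurred without particles. Each of these lists kept its sign on both arrays, which were read in channel order. A dye bias of the probes therefore cannot be told apart from a difference between water samples.

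**Figure D1:**
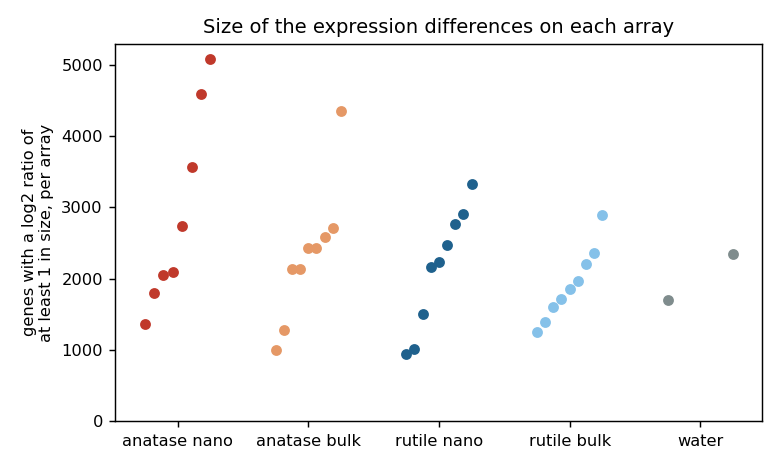
Number of genes with a log2 ratio of at least 1 in size on each array, with the arrays grouped by particle. The 2 water arrays, with 2341 and 1692 genes, lie within the range of the 35 treated arrays, 937 to 5088.

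The first question was which genes differ from water for each particle over its 3 doses. In worms exposed to nano-sized anatase, sod-3 (C08A9.1, chromosome X), which encodes a mitochondrial manganese superoxide dismutase, rose by 1.04 ± 0.21 on the log2 scale (SE, n = 8; limma adjusted p = 0.00573; higher on all 8 arrays). The metallothionein gene mtl-1 (K11G9.6, chromosome V), whose product binds metals, fell by 0.83 ± 0.25 (SE; limma adjusted p = 0.0491; lower on all 8 arrays). Among the genes with the same sign on all 8 arrays, the largest rises were in ttbk-8.1 (Y38H8A.3, 1.51 ± 0.31) and ttbk-8.2 (C39H7.1, 1.48 ± 0.26), which belong to the tau tubulin kinase family, in the insulin-like peptide gene ins-37 (F08G2.6, 1.37 ± 0.23) and in the C-type lectin gene clec-82 (Y54G2A.8, 1.35 ± 0.28), with limma adjusted p = 0.00653, 0.00209, 0.00187 and 0.00662. The largest falls under this limit were in the cystatin gene cpi-1 (K08B4.6), a cysteine protease inhibitor, by 1.44 ± 0.26, and in calm-1 (F30A10.1), by 1.09 ± 0.25, with limma adjusted p = 0.0028 and 0.0124. Other genes among these 10 largest rises were ttbk-2.1, the transporter gene snf-5, nsph-4.2, the cuticle collagen gene sqt-1, the T-box factor gene tbx-34 and phyh-1, with log2 changes of 1.22 to 1.39. The genes mtre-1, fipr-4, ptr-16, the copper chaperone gene cuc-1, the LIM domain gene pin-2, bath-39, grl-15 and suro-1 completed these 10 largest falls, with log2 changes of -1.09 to -0.90. Called changes of similar size on fewer arrays, such as those of hsp-16.20, clec-225 and col-177 given below, lie outside this ranking. Of these falls, the call of grl-15 ended in 23 of the 37 leave-one-out fits (log2 change from -1.29 to -0.52) and in 8 of 13 alternatives, and that of mtre-1 in 12 fits and in 6 of 12 alternatives. Those of the other 8 falls ended in at most 6 fits and 6 alternatives, and those of the 10 rises in 1 fit and at most 2 alternatives, apart from sqt-1 with 5 of each. Over all contrasts, leaving out nano 0.01 mg/L replicate 3 ended 48 of the 72 named calls, the most of any leave-one-out fit. On that array the sperm proteins had a list median of 2.31.

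In all, 451 genes were higher and 280 lower with nano-sized anatase (limma, adjusted p under 0.05), of 3416 at an unadjusted p under 0.05. The count was 38 without replicate 3 at 0.01 mg/L, 198 and 331 without replicates 4 and 5 at 0.1 mg/L, 423 without replicate 7 at 1 mg/L, 223 with the doubled scan kept in both places and 244 with slide as a random block. A block of the array-name numbers was not run for the particle means, although arrays that share such a number correlated across genes. The direction of every change rests on a reading of the channel order. The authors' own table is turned in the same way, but whether this is treated over water is not stated. With the opposite reading 280 genes would be higher and 451 lower. The call for sod-3 ended without replicate 3 at 0.01 mg/L (log2 change of at least 0.90 and highest adjusted p of 0.13 over the leave-one-out fits), and that of mtl-1 ended in 26 of the 37 leave-one-out fits and in 7 of 13 alternatives.

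Among the gene groups fixed before the data were examined, the sperm proteins moved most with nano-sized anatase. Of 74 measured genes of that list 26 rose, 0 fell and 48 did not pass (42 rose when adjusted over the list alone), with a median of 0.73 on the log2 scale. Examples are the major sperm protein genes msp-59, at 0.93 ± 0.21, and msp-81, at 0.86 ± 0.20; with 1 array left out they went down to 0.55 and 0.49 and both calls ended (highest adjusted p = 0.312 and 0.329). The list stood above the other genes in camera (adjusted p = 5.15e-15 with the preset correlation, adjusted p = 0.912 with an estimated correlation), and it had far higher medians on 2 anatase arrays, 2.31 on nano 0.01 mg/L replicate 3 and 2.56 on bulk 0.1 mg/L replicate 6, than on the other 35, where medians ran from -0.58 to 1.06. Of 159 cuticle collagens 14 rose, 1 fell and 144 did not pass (23 and 2 adjusted over the list alone), with a median of 0.29; col-95 rose by 1.19 ± 0.24 and col-149 by 1.15 ± 0.25, while col-177 fell by 0.95 ± 0.21. Of 145 C-type lectins, a family with members induced by pathogens, 12 rose, 2 fell and 131 did not pass (18 and 3 adjusted over the list alone), with a median of 0.19; clec-82 is among the former and clec-225 fell by 0.96 ± 0.24, a call that ended in 3 leave-one-out fits and in 6 of 13 alternatives. Of 46 histones 6 rose and 40 did not pass (10 adjusted over the list alone), with a median of 0.35, as in his-44 at 0.99 ± 0.19 and his-66 at 0.91 ± 0.17. Of 33 proteasome genes 3 rose and 30 did not pass (6 adjusted over the list alone), with a median of 0.35; pas-6 stood at 0.64 ± 0.16 and rpn-11 at 0.57 ± 0.15, and their calls ended in 2 and 5 leave-one-out fits and in 2 of 12 and 5 of 13 alternatives. Camera gave adjusted p = 0.000151 for the collagens, 0.00352 for the lectins, 2.84e-07 for the histones and 0.000445 for the proteasome genes, and adjusted p = 0.912 with an estimated correlation for each of the 4 lists. With slide as a random block the medians were 0.69 for the sperm proteins, 0.28 for the collagens, 0.20 for the lectins, 0.32 for the histones and 0.33 for the proteasome genes. Camera's call ended for the collagens without nano 1 mg/L replicate 8 (adjusted p = 0.0854) and for the lectins without nano 0.01 mg/L replicate 3 (adjusted p = 0.27).

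With nano-sized anatase 4 further lists were called. Of 77 ribosomal protein genes 3 rose and 74 did not pass (3 adjusted over the list alone), with a median of 0.12, rps-5 at 0.54 ± 0.14 among them. Of 37 genes of the mitochondrial respiratory chain 0 passed, in limma and adjusted over the list alone, with a median of 0.24; ucr-2.2 stood at 0.52 ± 0.16. Of 49 UDP-glucuronosyltransferases, enzymes that conjugate foreign compounds, 0 passed, with a median of -0.15, and ugt-65 stood at -0.86 ± 0.27. Of 192 F-box proteins 1 rose, 2 fell and 189 did not pass (0 adjusted over the list alone), with a median of -0.17; fbxa-73 rose by 0.61 ± 0.18 and fbxa-37 fell by 0.72 ± 0.18. These 2 calls ended in 14 and 5 of the 37 leave-one-out fits and in 6 of 11 and 3 of 12 alternatives, and that of rps-5 in 5 fits and in 4 of 12 alternatives. The camera values were adjusted p = 0.0369, 0.00523, 0.0478 and 0.00223 in that order, and adjusted p = 0.912 with an estimated correlation for all 4. The call of the ribosomal proteins ended in 4 of the 37 leave-one-out fits (highest adjusted p = 0.26, without nano 0.01 mg/L replicate 3) and that of the UDP-glucuronosyltransferases in 17 (highest adjusted p = 0.211, without nano 0.01 mg/L replicate 1). Of 12 alternatives 4 ended the call of the ribosomal proteins (medians from 0.01 to 0.38, highest adjusted p = 0.988), 6 that of the UDP-glucuronosyltransferases (highest adjusted p = 0.321) and 1 that of the F-box proteins (highest adjusted p = 0.124).

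Genes of oxidative and toxic stress moved in both directions with nano-sized anatase. Of 27 genes of oxidative stress defence 2 rose, sod-3 and the glutathione peroxidase gene gpx-3 (0.68 ± 0.16), and 2 fell, gpx-1 (-0.83 ± 0.22) and gst-10 (-0.89 ± 0.25), while 23 did not pass (2 and 2 adjusted over the list alone). The calls of gst-10, gpx-1 and gpx-3 ended in 7, 4 and 3 of 13 alternatives and in 5, 3 and 2 of the 37 leave-one-out fits (highest adjusted p = 0.358, 0.246 and 0.0976). Of 25 heat shock genes 1 rose, hsp-16.20 (1.25 ± 0.37), and 24 did not pass. Its call ended in 16 of the 37 leave-one-out fits (highest adjusted p = 0.216) and in 6 of 13 alternatives. Of 16 metal response genes aip-1 rose (0.68 ± 0.18; its call ended in 4 of 13 alternatives and 4 fits), mtl-1 fell and 14 did not pass. The rise of aip-1 was also called with bulk anatase, with log2 changes from 0.57 to 0.83 over the leave-one-out fits. That call ended in 28 of the 37 fits and in 7 of 13 alternatives. The stress genes hsp-16.2 (-0.28 ± 0.44), hsp-16.41 (-0.48 ± 0.42), hsp-70 (0.06 ± 0.25), hsp-4 (-0.11 ± 0.28), hsp-6 (0.49 ± 0.20) and mtl-2 (-0.29 ± 0.17) did not pass. The catalase genes ctl-1 (0.44 ± 0.16) and ctl-2 (0.24 ± 0.17), the cytochrome P450 genes cyp-35A2 (0.31 ± 0.19) and cyp-35B1 (0.25 ± 0.23), the yolk protein genes vit-2 (0.11 ± 0.38) and vit-6 (-0.14 ± 0.54) and the acyl-CoA synthetase gene acs-2 (0.27 ± 0.24) did not pass either. The camera values of the 3 lists were adjusted p = 0.48, 0.427 and 0.598. The genes gst-4, cyp-35A3 and fat-7 were not analysed here.

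**Figure D2:**
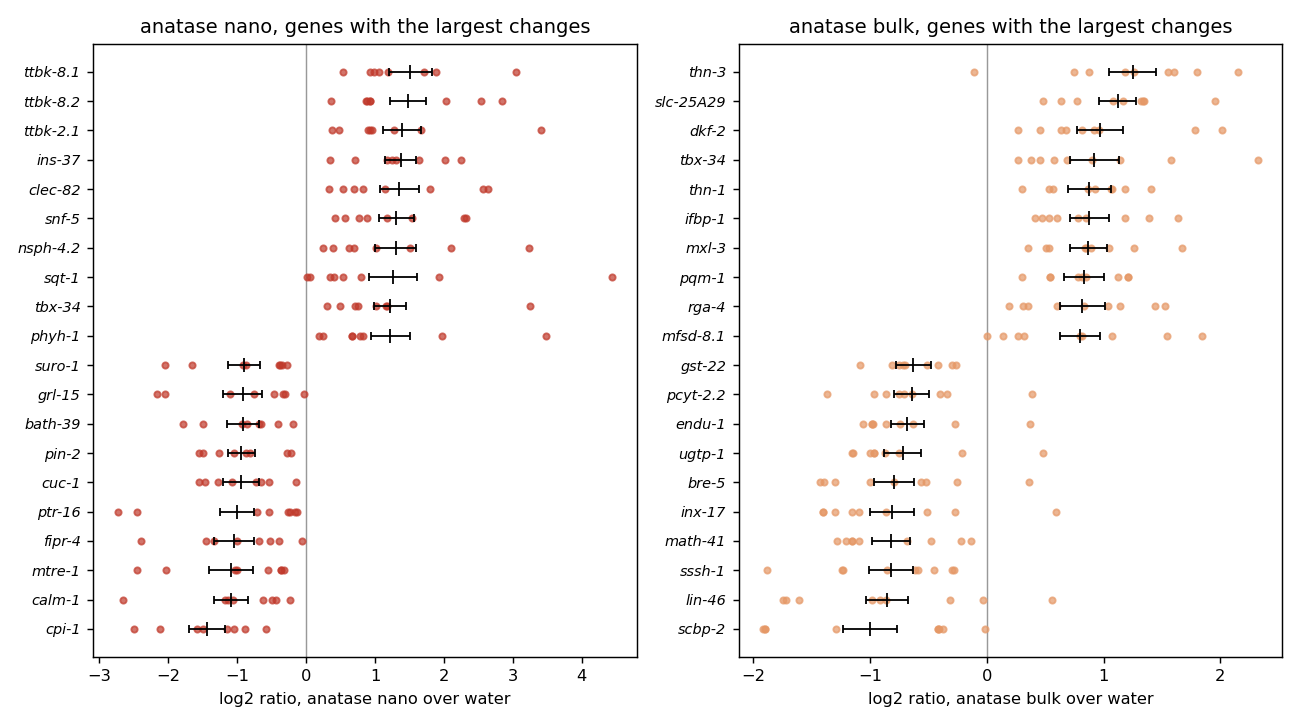
Log2 ratios to water of the genes with the largest changes, among those with the same sign on at least 8 arrays, with nano-sized (left) and bulk anatase (right), with 1 point per array and the fitted mean with its standard error. The largest rises shown are those of ttbk-8.1, 1.51, and of thn-3, 1.25.

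In worms exposed to bulk anatase, the thaumatin-family gene thn-3 (F28D1.4, chromosome IV) rose by 1.25 ± 0.20 on the log2 scale (SE, n = 9; limma adjusted p = 0.00219; higher on 8 of 9 arrays) and its relative thn-1 (F28D1.3) by 0.88 ± 0.18 (limma adjusted p = 0.0291; 9 of 9 arrays). The mitochondrial carrier gene slc-25A29 (C54G10.4, chromosome V) rose by 1.12 ± 0.16 (limma adjusted p = 0.00137; 9 of 9 arrays). The transcription factor genes mxl-3 (F46G10.6) and pqm-1 (F40F8.7), both known from the fasting and stress responses of worms, rose by 0.87 ± 0.16 and 0.83 ± 0.17 on all 9 arrays (limma adjusted p = 0.0126 and 0.0315). Among the genes with the same sign on at least 8 of the 9 arrays, the largest falls were in scbp-2 (2.0-fold lower; limma adjusted p = 0.0492; 9 of 9 arrays) and in lin-46 (-0.85 ± 0.18; limma adjusted p = 0.0315; 8 of 9 arrays), a gene of developmental timing. The protein kinase D gene dkf-2, tbx-34, ifbp-1, rga-4 and mfsd-8.1 were also among the 10 largest rises under this limit, at 0.80 to 0.97. The falls included sssh-1, math-41, the innexin gene inx-17, the glycosyltransferase gene bre-5, ugtp-1, endu-1, pcyt-2.2 and the glutathione S-transferase gene gst-22, at -0.82 to -0.63. In all, 35 genes were higher and 28 lower (limma), of 2318 at an unadjusted p under 0.05; it moved by over 1.5 times in 23 of the 37 leave-one-out fits, down to 3 without replicate 6 at 0.1 mg/L, and was 5 with slide as a random block. The calls of thn-3 and slc-25A29 held in all 13 alternatives run for them and in all 37 leave-one-out fits. Those of scbp-2, inx-17, gst-22, tbx-34, rga-4, sssh-1 and pcyt-2.2 ended in 23, 22, 25, 25, 28, 29 and 30 of these fits. Those of ugtp-1 and bre-5 ended in 12 and 9 fits, and the calls of these 9 genes in 6 to 11 of their 12 or 13 alternatives. For the other 9 genes named here as called, the numbers were 3 to 7 fits and 2 to 5 alternatives. For sod-3 and mtl-1 the changes were 0.49 ± 0.19 and -0.52 ± 0.23 (limma adjusted p = 0.233 and 0.289; 7 of 9 arrays each), and the tested differences between nano-sized and bulk anatase, 0.54 ± 0.28 and -0.31 ± 0.34, did not pass (limma adjusted p = 1 for each; 10 of 17 arrays each).

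With bulk anatase 6 lists were called, and of their members 0 passed over all genes tested. The 74 sperm proteins had a median of 0.40 on the log2 scale, with msp-78 at 0.60 ± 0.17, and 0 passed adjusted over the list alone. The 46 histones had a median of 0.31 and 5 rose when adjusted over the list alone, his-34 standing at 0.61 ± 0.16. The 159 cuticle collagens had a median of 0.18 and col-71 stood at 0.99 ± 0.31. The 33 proteasome genes had 0.21, with 2 higher adjusted over the list alone and pbs-5 at 0.53 ± 0.15. The 28 oocyte and eggshell genes had 0.19, with puf-7 at 0.54 ± 0.21, and the 49 UDP-glucuronosyltransferases -0.17, with 1 lower adjusted over the list alone and ugt-31 at -0.58 ± 0.16. The camera tests gave adjusted p = 5.41e-09, 1.87e-10, 0.000257, 0.00327, 0.0311 and 0.0329 in that order, and adjusted p = 0.912 with an estimated correlation for all 6 lists. The medians were 0.34, 0.30, 0.16, 0.23, 0.22 and -0.15 with slide as a random block. The calls of the first 4 lists held in every leave-one-out fit; that of the oocyte genes ended in 4 (highest adjusted p = 0.108, without bulk 0.1 mg/L replicate 5) and that of the UDP-glucuronosyltransferases in 5 (highest adjusted p = 0.088, without bulk 0.1 mg/L replicate 4). The latter 2 calls also ended in 2 and 1 of 12 alternatives.

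With nano-sized rutile 0 genes passed (limma), of 1293 at an unadjusted p under 0.05. The acyl-CoA synthetase gene acs-2, which acts in fatty acid oxidation, stood at 0.63 ± 0.22 (SE, n = 9; limma adjusted p = 0.555; above 0 on 9 of 9 arrays), and sod-3 and mtl-1 at 0.07 ± 0.19 and -0.16 ± 0.23. Of the lists, the 49 UDP-glucuronosyltransferases had a median of 0.20, with ugt-8 at 0.69 ± 0.22, and the 181 nuclear hormone receptors 0.11, with nhr-134 at 0.60 ± 0.17. The 159 cuticle collagens had -0.12, with col-84 at -0.91 ± 0.34, the 46 histones -0.09, with his-24 at -0.49 ± 0.18, and the 132 neuropeptides -0.10, with ins-38 at -0.80 ± 0.30. In these 5 lists 0 members passed, also adjusted over the list alone (limma). Camera gave adjusted p = 0.0428, 0.0333, 7.31e-05, 0.00617 and 0.011 in that order, and adjusted p = 0.912 with an estimated correlation for all 5. With slide as a random block their medians were 0.15, 0.12, -0.10, -0.04 and -0.07. In leave-one-out fits the calls of the 5 lists ended 5, 5, 1, 3 and 3 times in that order (highest adjusted p = 0.42, 0.253, 0.147, 0.58 and 0.74). The test of the neuropeptides turned its direction without nano 1 mg/L replicate 8. The UDP-glucuronosyltransferases and the nuclear hormone receptors each lost their call in 4 of 12 alternatives (highest adjusted p = 0.337 and 0.227).

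With bulk rutile the 28 oocyte and eggshell genes had a median of -0.40 on the log2 scale, with puf-7 at -0.72 ± 0.21 and the eggshell gene cpg-2 at -0.61 ± 0.23, and 1 was lower adjusted over the list alone. All 6 vitellogenins lay below 0, with a median of -0.59 and vit-3 at -1.07 ± 0.53. On single bulk rutile arrays the list median ran from -2.05 to 0.52 and lay above 0 on 4 of 9. It followed the number in the array names. On the 6 rutile arrays with number 3, nano-sized or bulk, it ran from -2.25 to -0.53. With number 1 and with number 2 it lay above 0 on 5 of 6. The 33 proteasome genes had -0.18, with pbs-6 at -0.51 ± 0.15, and the 46 histones -0.10, with his-41 at -0.53 ± 0.16. The 53 cytochrome P450s, which oxidise foreign compounds, had a median of 0.22, with cyp-35B1 at 0.65 ± 0.21 and above 0 on 9 of 9 arrays. The 49 UDP-glucuronosyltransferases had 0.18, with ugt-8 at 0.74 ± 0.22, and the 30 ABC transporters 0.23, with haf-9 at 0.56 ± 0.17. The 74 sperm proteins had 0.21, with spe-58 at 0.79 ± 0.27, and the 181 nuclear hormone receptors 0.11, with nhr-31 at 0.65 ± 0.18. Over all genes 0 passed (limma), of 1367 at an unadjusted p under 0.05, and besides the oocyte gene 0 members of these lists passed adjusted over the list alone. In camera these lists had adjusted p = 5.38e-08, 0.012, 7.31e-05, 0.00142, 0.000253, 0.00617, 0.00394, 0.000871 and 0.0228 in the order given, and adjusted p = 0.912 with an estimated correlation for all 9 lists. The medians were -0.43, -0.60, -0.18, -0.07, 0.20, 0.14, 0.21, 0.23 and 0.12 with slide as a random block. The calls of the oocyte genes, proteasome genes, P450s and ABC transporters held in every leave-one-out fit. That of the vitellogenins ended in 4 (highest adjusted p = 0.136, without bulk 0.1 mg/L replicate 6), that of the nuclear hormone receptors in 4 and those of the other 3 lists in 1 or 2. Of 12 alternatives, 3 ended the call of the vitellogenins (unflagged spots, the slide of the water arrays left out or turned; highest adjusted p = 0.361, medians up to -0.19) and 3 that of the nuclear hormone receptors (highest adjusted p = 0.409). Turning that slide also ended the call of the proteasome genes (median -0.04, adjusted p = 0.144), unflagged spots those of the P450s and the sperm proteins (adjusted p = 0.0549 and 0.119) and spot medians that of the UDP-glucuronosyltransferases (adjusted p = 0.199).

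**Figure D3:**
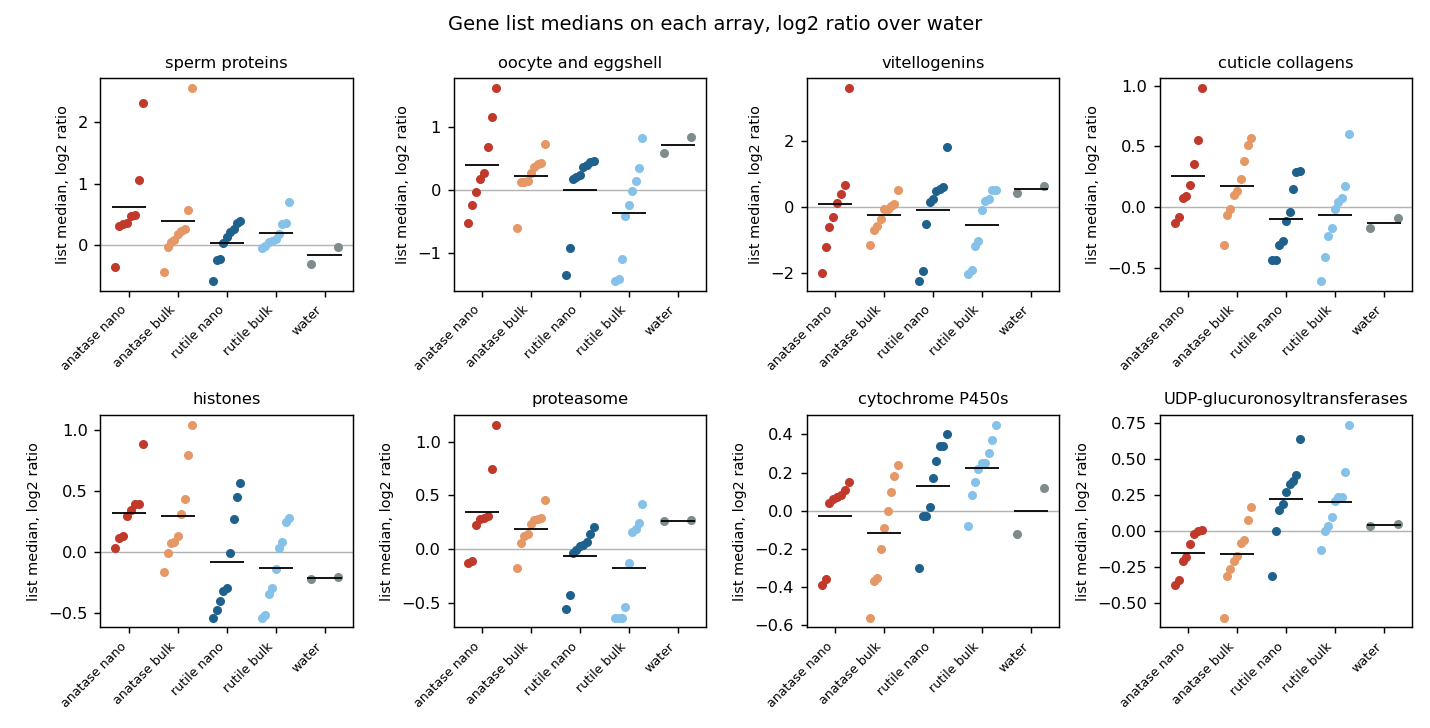
Median log2 ratio to water of 8 gene lists on each array, with the arrays grouped by particle. The sperm proteins reach 2.31 and 2.56 on 2 anatase arrays and lie between -0.58 and 1.06 on the other 35 arrays.

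The remaining lists were not called in any of the 4 particle means. They are the glutathione S-transferases, metal response, oxidative stress defence, heat shock proteins, the unfolded protein responses of the endoplasmic reticulum and of mitochondria, early embryo genes, moulting genes, lysozymes and antimicrobial peptides, pathogen response genes, fatty acid metabolism and the markers of neurons, body-wall muscle and intestine. Medians, means and tests differed in sign in 25 of the 290 list results, and of these 0 were called by camera. They were mostly lists with medians near 0, among them the vitellogenins with nano-sized anatase (median -0.02), the heat shock proteins with bulk anatase (median -0.07) and with nano-sized rutile (median 0.13), and the C-type lectins and ribosomal proteins with bulk rutile (medians 0.02 and 0.03).

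At single doses few genes passed. With nano-sized anatase at 0.1 mg/L, 4 genes rose and 0 fell: mdt-1.2 (3.16 ± 0.56; 2 of 2 arrays), the glutathione S-transferase gene gst-28 (2.68 ± 0.51; 2 of 3 arrays), H28G03.5 (2.14 ± 0.41; 3 of 3) and nssp-63 (1.70 ± 0.33; 3 of 3), each with limma adjusted p = 0.049. With bulk rutile at 0.01 mg/L, H09G03.1 rose by 4.17 ± 0.53 and oac-6 by 1.68 ± 0.32, while the lysozyme gene ilys-1 fell by 1.75 ± 0.28 and the cytochrome P450 gene cyp-13A11 fell by 1.77 ± 0.32 (limma adjusted p = 0.000109, 0.036, 0.00418 and 0.023; each on all 3 arrays). These 8 genes are named because they are all that passed, a choice made after their values were seen. With nano-sized anatase 26 genes were higher and 4 lower at 0.01 mg/L, where 2 arrays remained, and 19 were higher and 19 lower at 1 mg/L. For bulk anatase 0 genes passed at any dose (limma; 1067, 794 and 2441 at an unadjusted p under 0.05 from the lowest to the highest dose). For nano-sized rutile 0 passed (524, 552 and 196), and for bulk rutile 0 passed at 0.1 and 1 mg/L (307 and 437). Leaving out single arrays moved the count of nano-sized anatase at 0.01 mg/L from 10, without its replicate 3, to 351, without its replicate 1. At 0.1 mg/L it moved by over 1.5 times in 35 of the 37 fits, from 0 to 48, without replicate 5, and at 1 mg/L from 0, without replicate 9, to 100, without rutile nano 1 mg/L replicate 9. For bulk rutile at 0.01 mg/L it moved from 3 to 42, without replicate 3. Where 0 genes passed, the count reached 13 for nano-sized rutile at 0.1 mg/L, without replicate 6, and 5 for bulk anatase at 0.1 mg/L, without replicate 5, and was at most 3 elsewhere. The calls of mdt-1.2, gst-28, H28G03.5 and nssp-63 ended in 27, 34, 32 and 34 of the 37 fits, and those of oac-6, ilys-1 and cyp-13A11 in 7, 1 and 1. Alternatives ended that of mdt-1.2 in 4 of 11, those of gst-28, H28G03.5 and nssp-63 in 6 of 12 each, and those of oac-6, ilys-1 and cyp-13A11 in 4 of 11, 1 of 12 and 3 of 11.

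The title of the series asks for differences between nano-sized and bulk particles. For anatase, averaged over the 3 doses, 0 genes differed (limma; smallest adjusted p of 0.743; 453 at an unadjusted p under 0.05). The count was 0 with slide as a fixed block and with the replicate numbers as a block. Among the lists, the sperm proteins were higher with nano-sized than with bulk anatase (median difference 0.28, within-slide differences from -0.55 to 0.44, above 0 on 3 of 5 slides), with spe-12 at 1.35 ± 0.54. The C-type lectins (0.15; 0.00 to 0.23 within slides; clec-174 at 0.97 ± 0.35), the pathogen response genes (0.33; 0.04 to 0.59 within slides; dod-17 at 0.71 ± 0.29) and the respiratory chain (0.16; 0.05 to 0.58 within slides; atp-2 at 0.50 ± 0.30) also stood higher. The early embryo genes (-0.18; -0.32 to 0.38 within slides; sdz-38 at -0.92 ± 0.39) and the F-box proteins (-0.04; -0.18 to 0.07 within slides; fbxb-31 at -1.11 ± 0.34) stood lower. In all 6 lists 0 members passed, also adjusted over the list alone. Their camera tests had adjusted p = 2.56e-05, 0.029, 0.0339, 0.0228, 0.0022 and 0.0442 in that order, and adjusted p = 0.912 with an estimated correlation for all 6. With slide as a fixed block the adjusted p were 4.06e-07, 0.0236, 0.17, 0.299, 0.0695 and 0.183, and over the 15 alternatives the highest adjusted p were 0.0779, 0.112, 0.261, 0.299, 0.679 and 0.417 and the lowest 3.48e-07, 0.00783, 0.00346, 0.00609, 0.000361 and 0.00966. Without nano 0.01 mg/L replicate 3 the sperm proteins turned to the lower side (adjusted p = 0.354) and the lectins and early embryo genes lost their calls (adjusted p = 0.985 and 0.171). In all, the calls of the 6 lists ended in 4, 8, 7, 6, 1 and 11 of the 37 leave-one-out fits in the order given. Over the 15 alternatives they ended in 1, 4, 4, 3, 3 and 10, and the test of the early embryo genes turned its direction in 1.

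For rutile, averaged over the doses, 0 genes differed between nano-sized and bulk particles (limma; smallest adjusted p of 1; 172 at an unadjusted p under 0.05), and the count was 0 with each slide or replicate block. The oocyte and eggshell genes stood higher with nano-sized than with bulk rutile, with a median difference of 0.37 and within-slide differences from 0.08 to 0.85, above 0 on 5 of 5 slides; puf-7 stood at 0.58 ± 0.30 and cpg-2 at 0.50 ± 0.32. The respiratory chain (0.10; 0.02 to 0.62 within slides; sdhb-1 at 0.41 ± 0.23), the proteasome (0.13; -0.03 to 0.60; rpt-5 at 0.40 ± 0.27) and the ribosomal proteins (0.07; -0.06 to 0.26; rpl-6 at 0.36 ± 0.30) were also called higher. The sperm proteins (-0.18; -0.26 to 0.22; spe-39 at -0.77 ± 0.32) and the cuticle collagens (-0.02, mean -0.12; -0.20 to 0.47; col-44 at -0.87 ± 0.40) were called lower. In all 6 lists 0 members passed, also adjusted over the list alone. Camera gave adjusted p = 1.88e-06, 0.00509, 0.011, 0.0456, 0.000678 and 0.0251 in that order, and adjusted p = 0.912 with an estimated correlation for all 6. Blocking on slide gave adjusted p = 2.3e-06, 0.0108, 0.0195, 0.0695, 0.000269 and 0.0108, and over the 15 alternatives the highest adjusted p were 0.0262, 0.712, 0.999, 0.946, 0.00351 and 0.189 and the lowest 7.2e-09, 0.0032, 0.00459, 0.000184, 3.25e-06 and 5.6e-08. The call of the oocyte genes held in every leave-one-out fit, and the others ended in 3 to 10 of them, the ribosomal proteins turning to the lower side without nano 0.1 mg/L replicate 5 (adjusted p = 0.96). Of the 15 alternatives 9 ended the call of the ribosomal proteins (median down to -0.01) and 3 each those of the respiratory chain and the proteasome, among them leaving out or turning the slide of the water arrays; the tests of the ribosomal proteins and the respiratory chain turned their direction in 1 each. For the collagens 2 alternatives ended the call, and for the oocyte genes and sperm proteins 0.

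At single doses, nano-sized and bulk anatase differed in 2 genes at 0.01 mg/L, named here after their values were seen. C16A11.7 was 3.27 ± 0.54 higher with the nano-sized form (limma adjusted p = 0.0126; 4 of 5 arrays) and H34I24.1 was 2.22 ± 0.40 higher (limma adjusted p = 0.034; 5 of 5 arrays). The call of H34I24.1 ended in 8 of 16 alternatives (log2 difference from 1.68 to 6.02, highest adjusted p = 0.535) and in 4 of the 37 leave-one-out fits, and that of C16A11.7 in 2 of 15 and in 3. With slide as a fixed block the count was 4, with the replicate numbers of the titles as a block 101 and with the numbers of the array names as a block 2. The log2 deviations of the paired arrays from their group means correlated across genes at -0.20 and -0.38 under the title numbers. Under the numbers of the array names they correlated at 0.38 and 0.27. With 2 nano arrays the deviations mirror each other, so -0.38 and 0.38 are 1 value with its sign changed. These correlations therefore cannot decide between the numberings. Leaving out single arrays moved the count of the main fit from 0, without bulk 0.01 mg/L replicate 1, to 213, without nano 0.01 mg/L replicate 1. In the other 5 comparisons 0 genes passed (limma; 379 and 382 at an unadjusted p under 0.05 for anatase at 0.1 and 1 mg/L, and 311, 129 and 123 for rutile from the lowest to the highest dose). Without nano 0.1 mg/L replicate 5 the count for anatase at 0.1 mg/L was 15, and in the other 4 comparisons it stayed at 0 or 1 in every leave-one-out fit. The difference between nano-sized and bulk particles was itself compared between anatase and rutile, and 0 genes passed (limma; 252 at an unadjusted p under 0.05).

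The dose series asked whether expression changes with concentration, as a linear trend per 10-fold of dose. With nano-sized anatase F20B6.4, a gene without a symbol named here after its values were seen, fell by 1.77 ± 0.27 per 10-fold of dose (limma adjusted p = 0.00421; 5 of 5 arrays at the outer doses), and it was the only gene to pass, of 868 at an unadjusted p under 0.05. The sperm proteins had a median trend of -0.41 and the neuropeptides -0.21, while the oocyte genes had 0.24, the endoplasmic reticulum stress genes 0.18, the histones 0.15 and the proteasome 0.11. Camera gave adjusted p = 1.97e-09, 0.011, 0.0339, 0.0347, 0.0176 and 0.0228, and adjusted p = 0.912 with an estimated correlation for all 6 lists. Without nano 0.01 mg/L replicate 3 the trends of the sperm proteins and neuropeptides turned upward (adjusted p = 0.328 and 0.245), and each of the other 4 calls ended in 2 to 4 leave-one-out fits. The call of F20B6.4 ended in 2 fits and in 2 of 14 alternatives (highest adjusted p = 0.588). Of the 6 list calls that of the sperm proteins held in all 14 alternatives with the preset correlation, and each other ended in 1 or 2.

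With bulk anatase 0 genes had a trend (limma; 672 at an unadjusted p under 0.05). The histones had a median trend of 0.38 per 10-fold of dose, the neuropeptides 0.26, the sperm proteins 0.23, the cuticle collagens 0.19, the glutathione S-transferases 0.15 and the C-type lectins 0.07, while the oocyte genes had -0.20 and the ribosomal proteins -0.12. Camera gave adjusted p = 9.86e-15, 1.94e-10, 7.31e-05, 2.44e-07, 0.00028, 0.0375, 0.00889 and 0.00148 in that order, and adjusted p = 0.912 with an estimated correlation for all 8. The first 5 calls held in every leave-one-out fit, and the trend of the ribosomal proteins turned upward with unflagged spots alone (median 0.06). For the lectins the call ended in 7 of 14 alternatives (highest adjusted p = 0.551) and in 6 of the 37 leave-one-out fits, and those of the oocyte genes and ribosomal proteins in 1 of each. With nano-sized rutile 0 genes had a trend (limma; 220 at an unadjusted p under 0.05). The ribosomal proteins had -0.17, the oocyte genes -0.20, the UDP-glucuronosyltransferases -0.14, the cytochrome P450s -0.13 and the proteasome -0.08, and the lysozymes and the neuropeptides 0.10 each (adjusted p = 8.3e-09, 0.00392, 0.00553, 0.00392, 0.0375, 0.0339 and 0.00112; adjusted p = 0.912 with an estimated correlation for all 7). For the ribosomal proteins the call held in every leave-one-out fit but ended with unflagged spots (adjusted p = 0.0704), and the oocyte trend turned upward without nano 1 mg/L replicate 7 (adjusted p = 0.737). Without or with a turned slide of the water arrays the calls of the UDP-glucuronosyltransferases, P450s, lysozymes and neuropeptides ended (highest adjusted p = 0.897, 0.776, 0.66 and 0.946 over the 14 alternatives), and the test of the neuropeptides turned its direction in 1 alternative (median -0.01). The call of the proteasome ended in 5 alternatives. In leave-one-out fits the calls of the oocyte genes, UDP-glucuronosyltransferases and P450s ended in 2 each, of the lysozymes and neuropeptides in 3 each and of the proteasome in 4 (highest adjusted p = 0.737, 0.392, 0.31, 0.914, 0.737 and 0.907). With bulk rutile 0 genes had a trend (limma; 356 at an unadjusted p under 0.05), and the ABC transporters had -0.13, the metal response genes -0.14 and the ribosomal proteins -0.06 (adjusted p = 0.011, 0.0408 and 0.00804; adjusted p = 0.912 with an estimated correlation for all 3). The trend of the ribosomal proteins turned upward in 2 of 14 alternatives (median up to 0.06) and without bulk 1 mg/L replicate 9 (adjusted p = 0.859). Its call ended in 2 of the 37 leave-one-out fits, and over the 14 alternatives camera gave adjusted p of up to 0.712. The call of the metal response genes ended in 5 of 14 alternatives and in 5 of the 37 leave-one-out fits (highest adjusted p = 0.219). For the ABC transporters these numbers were 1 and 2. In these 4 dose series 0 members of the called lists passed over all genes.

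Anatase and rutile were compared within each particle size. Of the nano-sized forms 90 genes were higher and 91 lower with anatase (limma; 3148 at an unadjusted p under 0.05), and of the bulk forms 49 were higher and 48 lower (2921). Anatase and rutile were hybridised on separate slides, so crystal form and slide cannot be told apart. With slide as a random block both counts were 0 (limma). Leaving out single arrays moved the first by over 1.5 times in 19 of 37 fits, to 0 in 4 of them, without rutile nano 0.01 mg/L replicate 2, 0.1 mg/L replicate 5 and 1 mg/L replicates 7 and 8, and to 1168 without rutile nano 1 mg/L replicate 9. The second moved so in 26 of 37 fits, to 0 in 7 of them, anatase bulk 0.01 mg/L replicate 1 among the arrays left out, and to 184 without rutile nano 1 mg/L replicate 9.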

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

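The tests of the 3 results below were planned, and the settings that turn or leave out the slide of the water arrays were chosen after the results were seen. Differences between groups under the same contrast gave 3 results. Nano-sized anatase differed from nano-sized rutile in 181 genes, and of 100 splits of the same arrays 3 gave as many, so chance can be excluded only for independent arrays; the highest other split gave 1069 genes, which points to a structure of the samples. Bulk anatase differed from bulk rutile in 97 genes, with 1 split of 100, the real one, as large and a highest other of 1, so chance can be excluded under the same condition. These arrays do not meet it: those of the same number and slide correlated at a median of 0.38 across genes. Deviations from group means were also correlated, by the numbers of the array names. Those of 7 of 8 anatase and 9 of 9 rutile nano arrays correlated best with the bulk array of their own number. Crystal form and slides cannot be told apart, and with slide as a random block limma called 0 genes in both comparisons. Nano-sized and bulk anatase at 0.01 mg/L differed in 2 genes, C16A11.7 and H34I24.1; with 2 arrays on the nano-sized side no splits were counted.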

How the results depend on the processing

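The tests with all 38 arrays as deposited, with neither copy of the doubled scan, with spot medians, with unflagged spots, with a second loess and without or with a turned slide of the water arrays were chosen after the results were seen; the others were planned. No background correction, the scanner's processed signals and median centring in place of loess were not run, because the files hold values that are already corrected and normalised. The main counts were 76 genes over the 12 single doses, 731 for nano-sized anatase, 63 for bulk anatase, 0 for both forms of rutile, 2 for nano-sized against bulk particles at single doses, 1 for the dose trend of nano-sized anatase, 181 and 97 for anatase against rutile (nano-sized, bulk), and 65 called list results. In this order, the counts that moved by over 1.5 times were as follows. Scale normalization gave 23, 184, 17, 1 (single doses, nano-sized against bulk) and 1 (anatase against rutile, nano-sized). Without the filter on dim probes the counts were 178, 412, 9, 1 (bulk rutile), 11, 2, 34 and 12, and 15 for the dose trend of bulk rutile. Without a dye term they were 26 for bulk anatase, 90 and 19 for anatase against rutile. Separate fits per crystal form gave 3, 171, 3, 0 and 0 up to the dose trend. Slide as a random block gave 37, 244, 5, 4, 0 and 0. Slide as a fixed block gave 4 genes for nano-sized against bulk particles at single doses and 7 of 12 called lists in nano-sized against bulk, and for the former the block of title numbers gave 101 genes and that of array-name numbers 2. All 38 arrays as deposited gave 30, 223, 3, 0 for the dose trend, 0 and 13; neither copy of the doubled scan gave 1 for nano-sized against bulk at single doses. Spot medians gave 270 for single doses, 2 for the dose trend and 0 for bulk anatase against bulk rutile, and a second loess 36 for bulk anatase. Without the slide of the water arrays the counts were 102 for bulk anatase, 1 for bulk rutile, 1 for nano-sized against bulk at single doses, 1377 and 251; with that slide turned they were 219, 135, 3 for nano-sized rutile, 13 for bulk rutile, 1825 and 305. With an estimated correlation 0 lists were called. Leaving out 1 array at a time, the ranges were 43 to 396 for single doses, 38 (without anatase nano 0.01 mg/L replicate 3) to 908 (without its replicate 1) for nano-sized anatase, 3 (without anatase bulk 0.1 mg/L replicate 6) to 90 for bulk anatase, 0 to 4 for nano-sized rutile (without 0.1 mg/L replicate 6) and 0 to 4 for bulk rutile (without 0.01 mg/L replicate 3). They were 0 to 3 for nano-sized against bulk anatase, 0 to 213 at single doses, 0 to 16 for the dose trend of nano-sized anatase, 0 to 2 for that of nano-sized rutile and 0 to 1 for that of bulk rutile, 0 to 1168 and 0 to 184 for anatase against rutile, and 0 to 2 for the difference between the nano-sized and bulk contrasts. The cause of these changes was not tested, except that anatase and rutile lie on separate slides. The median of all genes stayed between -0.10 and 0.09 on the log2 scale in every setting. Of the 65 called list results 0 kept their call with the estimated correlation, and camera was not run with slide as a random block. Over the other alternatives 25 kept their call in every one, and 16 also in every leave-one-out fit. The direction turned in an alternative for 6.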

Other observations

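All tests of the 3 patterns weighed below were chosen after the results were seen, while the splits of the arrays were planned. Some gene groups moved one way on the arrays that share the number after the dose in the array names, which runs from 1 to 3 across particles and doses. On the 6 rutile arrays with number 3, vitellogenin medians ran from -2.25 to -0.53 and those of the cuticle collagens from -0.61 to -0.02, while lysozymes and antimicrobial peptides had 0.03 to 0.61. On the 6 rutile arrays with number 1 the lysozymes had -0.68 to -0.24, the cytochrome P450s 0.15 to 0.45 and the genes of the unfolded protein response of the endoplasmic reticulum 0.20 to 0.39. On the 6 anatase arrays with number 1 the oocyte and eggshell genes had 0.26 to 1.15 and the proteasome genes 0.27 to 0.75. These groups were read off after the values were seen, and no test compared the numbers. Apart from the lysozymes with number 1, each range overlapped that of another number of the same crystal form. On several slides all arrays carry a single number, so slide and number partly coincide.

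Arrays that share this number had similar log2 ratios. Across genes, which are not independent replicates, arrays of the same number on different slides and of different groups correlated at a median of 0.17, against -0.04 for different numbers, a difference just over the bound of 0.2. The medians were 0.23 against 0.03 for anatase and 0.13 against -0.09 for rutile. Slide alone cannot be judged. Its median was -0.12 over 8 pairs of arrays of different number on one slide, all with opposite dyes. A slide effect in channel order would change its sign between such arrays. Particle and dose, with -0.11 over 34 pairs, are argued against only weakly. Of these pairs 11 shared a dye, and a dye bias would lower the median of the others. Arrays of the same number that also shared a slide had a median of 0.38. It was higher than on different slides for rutile, at 0.52, but not for anatase, at 0.21. Slide may thus add to the pattern for rutile. The dye of the treated sample stays open. Same-number arrays with opposite dyes had a median of 0.15, with 0.02 for anatase and 0.20 for rutile. One water sample or culture batch per number, besides slide and dye, may account for part of the ratios, as a hypothesis.

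On the slide of the water arrays, 2 rutile arrays correlated little with the other rutile arrays of their number, at 0.08 or lower over 8 pairs. All rutile pairs of the same number on different slides ran from -0.27 to 0.52, with a median of 0.13. These 2 arrays are therefore not clearly set apart. Exchanged channels are argued against by the spike-in difference, which was at least 3.14 on that slide and at least 1.21 on the others, with the same sign. Whether treated and water RNA were exchanged there cannot be told apart from a batch difference, since the median correlation across genes with the other arrays of their number was -0.03. No biological explanation was tested.

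Sperm genes were far higher on 2 anatase arrays, nano 0.01 mg/L replicate 3 and bulk 0.1 mg/L replicate 6, which share a slide and a number. A water sample poor in sperm transcripts and shared by all arrays of that slide and number is argued against by the other 2 arrays. Their highest list median was 0.31. The labels do not say which arrays shared water RNA, so water poor in sperm transcripts on the 2 high arrays alone stays open. Particle and dose are argued against by the other arrays of the 2 groups, at 0.47 or lower. Dye bias is argued against by list medians of opposite sign in channel order, the lower at -2.56. One treated RNA on both arrays is argued against only weakly, by a correlation of 0.6 across genes under a bound of 0.7 that is arbitrary, where the doubled scan had 0.87 in size over the same gene values (0.77 across single spots). More sperm-bearing worms in these cultures may be the source, which was not tested. Without the nano array the count of nano-sized anatase was 38.

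Splits of the same arrays exclude chance only if the arrays are independent. Arrays of the same number and slide correlated at a median of 0.38 (0.21 for anatase, 0.52 for rutile), and the consensus correlation within slides was 0.17. For nano-sized anatase 1 of 100 splits, the real one, gave as many as 731 genes (highest other 382), and for bulk anatase 1 of 100 gave 63 (highest other 13), so chance can be excluded for both under that condition. With slide as a random block the counts were 244 and 5, and with 1 array left out 38 and 3 at the lowest. Where the real count was 0 every split is as large by construction, which says nothing about chance: 100 of 100 for nano-sized rutile (highest other 629), bulk rutile (5), nano-sized against bulk anatase (2) and rutile (27), and the difference of these contrasts (8). The 629 genes came from turning rutile nano replicates 6, 7 and 9, of which the first 2 carry number 3 and the last lies on the slide of the water arrays, and this points to a structure of the samples. For the called lists 21 of 100 splits were as large for nano-sized anatase (9 lists, highest other 11), 58 for bulk anatase (6, 11), 72 for nano-sized rutile (5, 10), 25 for bulk rutile (9, 13), 44 for nano-sized against bulk anatase (6, 10) and 74 for rutile (6, 11), so chance cannot be excluded for these.

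At single doses the arrays allow 4 splits, too few for a share under 0.05. Nano-sized anatase had 4 genes at 0.1 mg/L (highest other 22, 2 splits as large) and 38 at 1 mg/L (highest other 0, 1 split), and bulk rutile at 0.01 mg/L 4 (highest other 13, 3 splits). In the other single doses of bulk anatase, nano-sized rutile and bulk rutile the real count was 0 and the highest others 0 to 2, so all 4 splits are as large by construction. The 10 splits of nano-sized against bulk particles at single doses and of the dose trends, apart from those of anatase with 2 nano arrays, are also too few: the real counts were 0, the highest others 0 or 1, and all 10 are as large by construction.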
